A study of Homo sapiens with 4 samples.

How the data were processed

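Poly(A)-selected RNA libraries of p53-null HCT116 cells were sequenced as read pairs on an Illumina instrument, per the labels' protocols. There were 4 libraries in 4 groups, taken from the labels: vector, p53WT, M133T with 24 hours of arsenic trioxide and R282W with 24 hours of arsenic trioxide. The label of the R282W library says that it was sourced from an earlier series. Per the submitters' processing notes, the tools were FastQC 0.10.1, cutadapt 1.9.1, HISAT2 2.0.1 and HTSeq 0.6.1, and the build was hg38. The annotation release and the step that made length-scaled values are not given in the sources used here.

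Each deposited file holds 1 value per gene symbol, mostly with 2 decimals, which was read as FPKM because low values were inversely proportional to annotated gene length and the columns summed to different totals. The file headers name no unit, so this reading rests on the values. Read counts were not used here, whereas the design written before the data were examined assumed them. The count-based scaling, the counting intervals and the thinning of that design were therefore not run, and the absolute depth is unknown. The smallest recurring step of FPKM times exonic length, over genes of 400 to 1000 bases, was used only as a hint of relative depth. A few symbols carry more decimals, such as RN7SL1, and look like averages of several rows. Genes with near-identical copies or overlapping neighbours are named as uncertain. Whether the authors' quantification used strand is not given in the sources used here.

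Each file had 55694 rows. The 28 rows whose symbols had been turned into dates, including 2 repeated names, were left out, which left 55666 symbols. In the R282W file 312 rows stood in another order than in the other files, and 103 of the 125 p53 target list members were among them, so files were joined by symbol and never by row. Joined by position these rows gave an r of -0.02 with M133T, and joined by symbol 0.991. Of the genes kept, 12899 (87.8%) were matched to GENCODE 29 on GRCh38, through current or older symbols, for positions, types and exonic lengths. Levels of genes that differ by sex chromosome were not examined.

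Genes with at least 1 FPKM in at least 1 library were kept, 14688 in all. The deposited FPKM values were used without further scaling, and log2 ratios were computed from FPKM + 1. Factors from other scalings lay within 0.1 of the vector library on the log2 scale, with the largest shift -0.099 for p53WT by the median of ratios. Genes were counted as higher or lower when they differed at least 2-fold on that scale. With 1 library per group no test, standard error or p-value could be computed, and 6 comparisons were made. For each of 26 gene lists fixed before the data were examined, and for the 5 p53 lists together, the median ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression, when at least 5 members were measured. The share of unchanged libraries expected in correlations and overlaps came from 100 simulations whose noise was resampled from the R282W to M133T differences. These include any real difference between the mutants, which may overstate noise. The same noise was given to every library, while that of p53WT and vector is unknown without replicates and may be larger. Whether the simulated values are too high or too low is therefore not known.

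The rule for named genes was fixed before the data were examined. It took 11 preset genes, the 8 highest and 8 lowest genes of each comparison and up to 4 members of each list described. Its minimum of 200 reads for the highest and lowest genes was replaced by an FPKM of at least 10 when multiplied by exonic length in kilobases, which restricts them to genes matched to GENCODE. Its minimum of 20 reads was replaced by 1 FPKM. Both replacements were forced by the unit and chosen after the data were seen. Some of the genes that the rule picks are not reported here. The text names only some of the others, and the small RNA sum, the markers of other cell types and the shared genes were picked after their values were seen. The members of the lists came from general knowledge.

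The ratio, the size rule and the list percentile were tried on simulated libraries for p53WT against vector over 14688 genes, with normal noise sized from the median absolute differences between the mutants. The changed genes were drawn only from genes with a mean of at least 5 FPKM over the libraries. All 50 genes changed 4-fold, all 50 changed 8-fold and all 50 changed 16-fold were recovered, as were 21 of 50 changed 2-fold, and 3 of 14488 unchanged genes were counted. Recovery of lower genes, whose ratios the added 1 FPKM shrinks, was not tried. That noise lacks the wide tails of the real differences, since 263 genes differed 2-fold between the mutants and the resampled noise gave 26.9 shared higher and 58.8 shared lower genes, so the 3 understates the genes that would be counted without a difference. A list raised 4-fold stood at percentile 100, and 2 of 100 lists of unchanged genes fell outside the central 95%. Those 100 lists were random draws with independent noise, so a low number follows by construction. It does not cover lists whose members vary together. Alternatives were median-of-ratios scaling, equal sums, a trimmed mean over the 3 libraries of the series, and no filter, all planned for counts and applied here to FPKM, and a minimum of 5 FPKM, a pseudocount of 0.1, a trimmed mean over 4 libraries and protein-coding genes only, which were chosen after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.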

Results

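RNA was sequenced from HCT116 cells, a human colon carcinoma line, in a derivative without p53. The 4 libraries, 1 per group, came from cells carrying an empty vector, cells stably expressing wild-type p53 (p53WT), and cells stably expressing the p53 mutants M133T or R282W and treated for 24 hours with arsenic trioxide (ATO). The labels call the arsenic-treated mutants PANDAs. Arsenic trioxide binds cysteines and can stabilise the fold of some p53 mutants. The vector and p53WT cells were not treated. The R282W library was taken from an earlier series, according to its label. Values are FPKM (fragments scaled by transcript length and library size), a unit inferred from the values, and they summed to 684119 for p53WT, 681476 for M133T, 656578 for R282W and 691449 for vector. The number of sequenced fragments is unknown. The smallest steps between low values put the depth of p53WT at about 0.714 of that of the other libraries, as a rough hint. Levels of at least 1 FPKM were reached by 13425 symbols in p53WT, 13278 in M133T, 13205 in R282W and 13589 in vector. No group had a replicate, so no difference here was tested, and "higher" and "lower" describe 2 libraries and not 2 conditions. No vector cells with arsenic and no mutant cells without arsenic were analysed here, so mutant p53 and arsenic cannot be separated. Log2 ratios, and all statements and counts of 2-fold, are on the log2(FPKM + 1) scale, which understates differences of low genes. Some genes said to differ by less than 2-fold therefore differ by more in plain FPKM. A list is said to lie outside the random range when its median fell outside the central 95% of medians of 10000 random lists matched on expression. Members of a list can vary together, which random lists do not mimic. Lying outside the range is therefore a description and not a test.

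**Figure D1:**
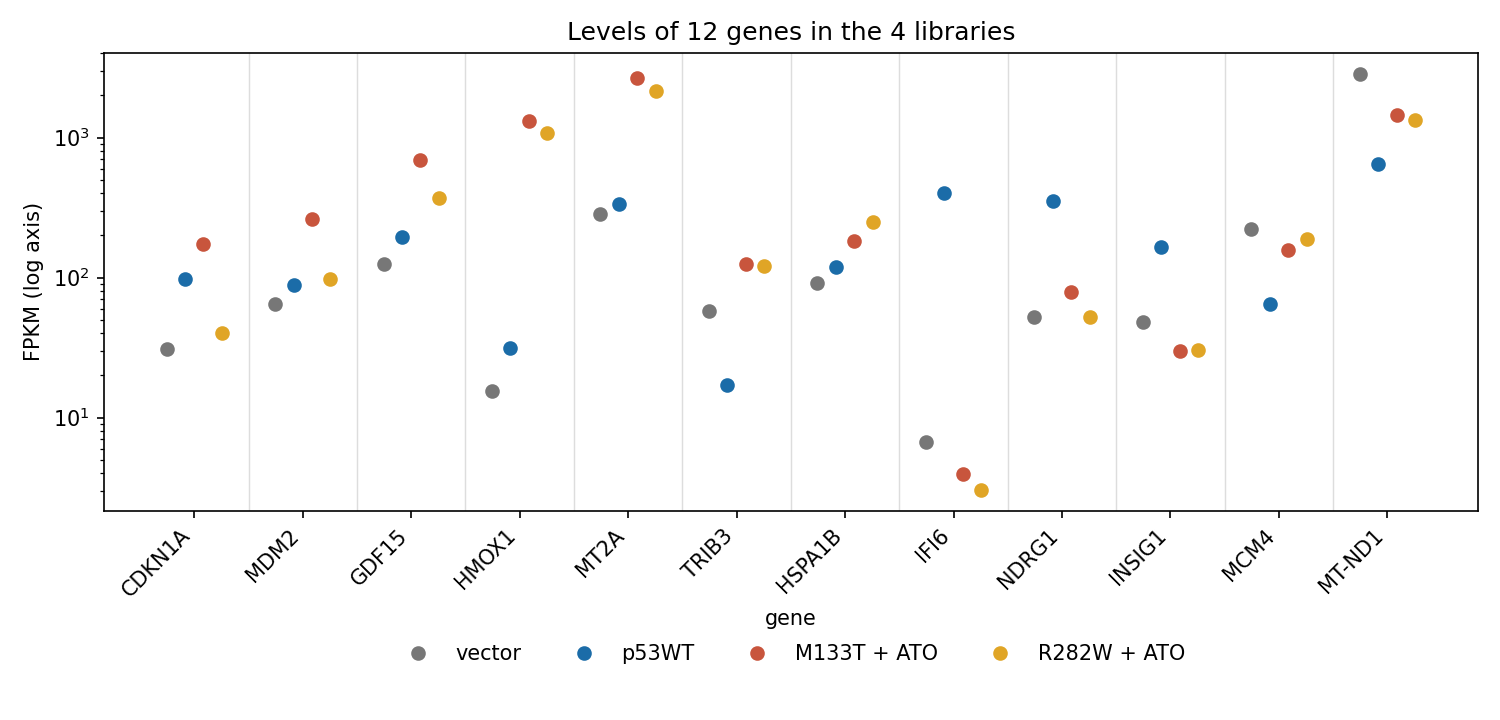
Levels of 12 genes in the 4 libraries, with FPKM on a log axis and 1 point per library. CDKN1A was at 174 FPKM in M133T and 40.3 FPKM in R282W, and IFI6 was at 400 FPKM in p53WT and 6.69 FPKM or lower in the other libraries.

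The first comparison asks which genes differ when wild-type p53 is expressed in p53-null cells. In p53WT, the cell cycle inhibitor CDKN1A (p21; chromosome 6, 36676460 to 36687339, GRCh38) stood at 97.9 FPKM against 30.9 in vector, a log2 ratio of 1.63. TP53INP1 and BTG2, further growth-restraining p53 targets, were higher by 1.65 and 1.52. The differences extended well beyond p53 targets. Interferon-stimulated genes were far higher, with IFI27 at 342 FPKM against 0.72, while genes of DNA replication were lower, with MCM4 at 65.1 FPKM against 222. Of 14688 genes, 500 were at least 2-fold higher and 522 at least 2-fold lower in p53WT, of which 253 and 271 were protein-coding genes of GENCODE 29. Which direction held more genes depended on the scaling, with 580 higher and 426 lower by the median of ratios and 513 and 499 by equal sums.

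Across all p53 targets the median log2 ratio of p53WT to vector was 0.20, outside the random range, with 86 of 112 measured members above 0, 7 at least 2-fold higher and 1 at least 2-fold lower. Arrest and feedback targets had the highest median of the 5 p53 lists at 0.62, with 10 of 12 above 0 and 3 at least 2-fold higher. ZMAT3, an RNA-binding p53 target, had a ratio of 0.82, the secreted factor GDF15 one of 0.65, and MDM2, the ubiquitin ligase that limits p53, one of 0.45. Metabolic and redox targets had a median of 0.52 (15 of 18 above 0), with the polyamine enzyme SAT1 at 764 FPKM against 364 (ratio 1.07), the antioxidant gene SESN1 at 0.89, and its relative SESN2 lower at -1.24. Death targets had a median of 0.16, just outside the random range, and none of 16 differed 2-fold on the log2(FPKM + 1) scale. Among them TP53I3 stood at 0.95 (15.3 FPKM against 7.44, just over 2-fold in plain FPKM), FAS at 0.43, BAX at 0.12 and BBC3 at -0.06. The repair targets, with a median of 0.16 over 7 genes, lay inside the random range, and FDXR, a mitochondrial reductase of the metabolic list, had a ratio of 0.14. The other p53 targets had a median of 0.15 over 59 genes, outside the random range, with SERPINB5 at 1.27 and HES2 at 1.27.

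Interferon-stimulated genes had a median log2 ratio of 2.33, and 18 of 19 measured members were at least 2-fold higher in p53WT. IFI27 had a ratio of 7.64, IFI6 5.70, BST2 4.62 and IFIT1 4.36. Hypoxia genes had a median of 1.27 with 10 of 14 at least 2-fold higher, among them ANKRD37 (3.59), NDRG1 (2.72), ADM, which encodes adrenomedullin (2.47), and the carbonic anhydrase CA9 (2.22). All 16 cholesterol synthesis genes were above 0, with a median of 0.92. INSIG1 (1.75), HMGCS1 (1.71), MSMO1 (1.70) and SQLE (1.36) differed most in that list. Colon epithelial markers had a median of 0.43, with the transcription factor ELF3 at 1.58 and the keratin KRT19 at 1.09. NF-kB targets had a median of 0.36 (7 of 7 above 0, none at 2-fold), and ribosomal protein genes one of 0.14 (38 of 50 above 0). These 6 lists lay above the random range. Outside the lists, IFITM1 (4.63), TNFRSF6B (3.63) and the small RNA RN7SL2 (3.62) were among the 8 genes with the highest ratios. OAS1 (3.89), a member of the interferon-stimulated list, was also among them. RN7SL2 shares reads with near-identical copies and is uncertain. Named small RNAs summed to 3529 FPKM in p53WT against 673 in vector, 916 in M133T and 746 in R282W.

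Lower in p53WT were G1/S and replication genes, with a median of -1.25, 20 of 29 at least 2-fold lower and none above 0. CDC45 (-1.63), MCM2 (-1.56) and E2F2 (-1.53) followed MCM4 (-1.75). All 34 G2/M and mitotic genes were below 0, with a median of -0.74, and FOXM1 (-1.24), TTK (-1.09), AURKB (-1.07) and PLK1 (59.0 FPKM against 119) were lowest. Integrated stress response genes had a median of -1.15, with 9 of 16 at least 2-fold lower. They included CHAC1 (-2.87), the asparagine synthetase gene ASNS (59.2 FPKM against 240), the serine synthesis gene PSAT1 (-1.97) and TRIB3 (-1.70). All 13 mitochondrially encoded genes were below 0, with a median of -1.37, and MT-ND1 stood at 645 FPKM against 2856. The mitochondrial share of summed FPKM was highest in vector, at 10.3%. It was 4.54% in p53WT, 6.38% in M133T and 6.31% in R282W. These 4 lists lay below the random range. GRIK4, a glutamate receptor gene, had a ratio of -3.14, the lowest of the named genes with reads in both libraries. It was at 15.2 FPKM in vector against 0.84 in p53WT, 0.42 in M133T and 0.44 in R282W. For this gene the single vector library stood apart from all the others. MKKS (-2.79), ARHGAP11B (-2.48) and PTOV1-AS1 (-2.77) overlap or resemble other genes and are uncertain, and ECE2, BIVM-ERCC5 and CXCR5 were listed at 0 in p53WT. For MKKS, ARHGAP11B, PTOV1-AS1, ECE2 and BIVM-ERCC5 the single p53WT library stood apart from all the others. MKKS was at 8.94 FPKM in p53WT against 67.6 in vector, 72.5 in M133T and 87.5 in R282W. ECE2 was at 5.92 FPKM in vector, 5.13 in M133T and 5.43 in R282W. Whether preparation or quantification set p53WT apart here was not tested.

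Inside the random range for p53WT were metallothioneins and the zinc transporter gene (median 0.24 over 5 genes), heat shock genes (-0.15 over 12), ER chaperone genes (within 0.01 of 0 over 14), Wnt targets (-0.26 over 6), histone genes (-0.33 over 12) and reference genes (-0.07 over 11). NRF2 targets, the antioxidant genes of that factor, had a median within 0.01 of 0 over 19 genes, with HMOX1 at 0.97 and the cystine transporter gene SLC7A11 at -1.70. Of markers of other cell types, 1 of 8 fibroblast, 3 of 8 blood cell, 0 of 5 endothelial and 1 of 6 hepatocyte markers reached 1 FPKM in any library. Lysozyme (LYZ) was at 4.24 FPKM in p53WT against 0.38 in vector, and SERPINA1 at 5.57 against 1.81. Counts of higher genes ranged from 253 to 808 and counts of lower genes from 271 to 1014 over the alternative settings.

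**Figure D2:**
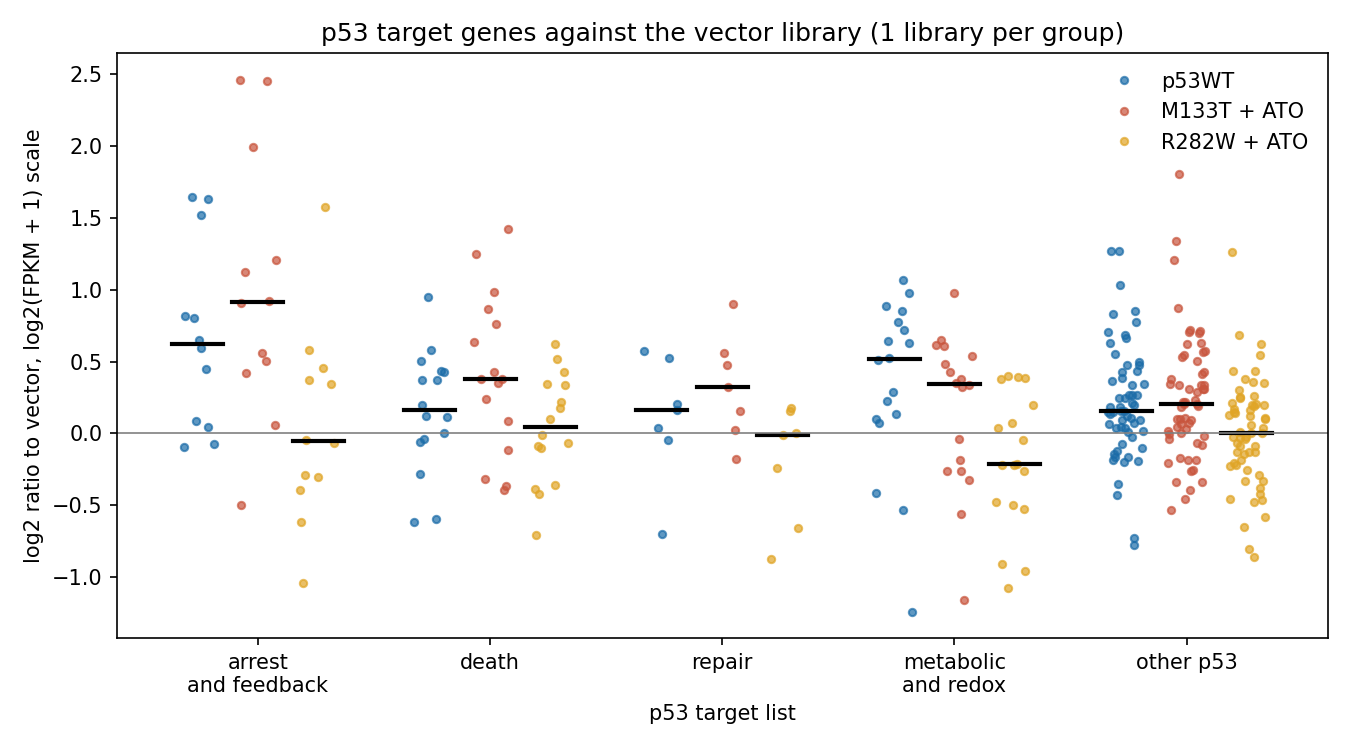
Log2 ratios to vector of the measured members of the 5 p53 target lists, 1 point per gene and a bar at each list's median, for p53WT, M133T with ATO and R282W with ATO. For the arrest and feedback list the medians were 0.62, 0.91 and -0.05 in that order.

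The second comparison, M133T with arsenic against vector, asks which genes differ in cells with this arsenic-treated mutant. CDKN1A was at 174 FPKM against 30.9 in vector (log2 ratio 2.45), GDF15 at 689 against 124 (2.46) and MDM2 at 262 against 65.0. The heme oxygenase gene HMOX1 (chromosome 22, 35380361 to 35394214), a marker of oxidative and metal stress, was at 1312 FPKM against 15.5 (6.31), and the metal-binding metallothionein MT2A at 2654 against 285 (3.22). In total 504 genes differed at least 2-fold, 222 of them higher in M133T and the rest lower. Of the protein-coding genes, 71 were higher and 124 lower.

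Over all p53 targets the median ratio of M133T to vector was 0.32, outside the random range, with 83 of 112 above 0, 10 at least 2-fold higher and 1 lower. Each of the 5 p53 lists lay above the random range. The arrest and feedback list had a median of 0.91 with 5 of 12 members at least 2-fold higher, including BTG2 (1.21) and ZMAT3 (1.12). Death targets had a median of 0.38, and 2 of 16 were at least 2-fold higher, the growth regulator PHLDA3 (1.43) and the death receptor gene FAS (1.25). The receptor genes TNFRSF10D (0.99) and TNFRSF10B (0.87), BAX (0.76) and BBC3 (0.64) were higher by less, and TP53I3 stood at 0.24. For repair targets the median was 0.32, with the ribonucleotide reductase gene RRM2B at 0.90. Metabolic and redox targets had a median of 0.35 with 11 of 18 above 0, SESN1 at 0.98, TIGAR at 0.62, FDXR at -0.18 and CPT1C lower at -1.16. Other p53 targets had a median of 0.21, with ABHD4 at 1.34 and SERPINB5 at 1.20.

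Metallothioneins and the zinc transporter gene had the highest median of all lists in M133T, 2.76 over 5 genes, with MT1X at 2.88, MT1E at 2.76 and SLC30A1 at 0.92. NRF2 targets had a median of 1.22, and 10 of 19 were at least 2-fold higher, among them the glutathione synthesis gene GCLM (2.22), the ferritin gene FTH1 (1.64) and SRXN1 (1.60). Heat shock genes had a median of 0.49 with 10 of 12 above 0, led by HSPA8 (0.99) and HSPA1B (0.97). HSPA1A and HSPA1B are near-identical copies, so their separate values are uncertain. All 16 integrated stress response genes were above 0, with a median of 0.52, and NUPR1 (1.60) and TRIB3 (1.11) were at least 2-fold higher. Ribosomal protein genes had a median of 0.07, just above the random range. G1/S and replication genes had a median of -0.37 with 27 of 29 below 0, and MCM7, which hosts microRNAs in its introns, was lowest at -1.48. MCM7 was at 222 FPKM in vector against 96.5 in p53WT, 79.0 in M133T and 90.0 in R282W, so vector stood apart. G2/M genes had 17 of 34 members on each side of 0. Also below the random range were the mitochondrially encoded genes (median -0.67, 13 of 13 below 0), histone genes (-0.87, 12 of 12 below 0) and cholesterol synthesis genes (-0.27, with LSS at -1.18). Interferon-stimulated genes (-0.16), NF-kB targets (-0.09), hypoxia genes (-0.04), Wnt targets (-0.18), reference genes (0.09) and colon epithelial markers (0.10) lay inside it.

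Among the 8 lowest genes in M133T were the circadian transcription factor DBP (5.63 FPKM, ratio -1.97), WNT16 (-1.95), the phosphatase gene CTDSP1 (-1.90) and GRIK4 (-3.51). The hemoglobin genes HBB (listed at 0 in M133T, 12.6 FPKM in vector) and HBA2 (-2.11), the mitochondrial rRNA MT-RNR1 (-1.96) and SLX1B (-3.09) were also there. HBA2 and SLX1B have near-identical copies and are uncertain. ZNF469, at 10.1 FPKM against 1.35 (2.25), was also among the 8 highest genes. Counts ranged from 71 to 427 for higher and from 124 to 721 for lower genes over the alternative settings.

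The third comparison sets R282W with arsenic against vector. HMOX1 was at 1086 FPKM against 15.5 (6.04), MT2A at 2156 against 285 (2.92) and GCLM at 92.9 against 17.9 (2.32). Most p53 targets differed from vector by less than 2-fold, as in the other libraries. They numbered 108 of 112 in R282W, 104 in p53WT and 101 in M133T. CDKN1A stood at 40.3 FPKM against 30.9 (0.37), MDM2 at 97.7 against 65.0 (0.58), while GDF15, at 373 against 124 (1.58), was among the exceptions. Genes at least 2-fold higher numbered 196 and lower 316, of which 50 and 150 were protein-coding.

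Over all p53 targets the median ratio of R282W to vector was -0.02, inside the random range (-0.08 to 0.06), with 54 members above and 58 below 0, 2 at least 2-fold higher and 2 at least 2-fold lower. Arrest and feedback targets had a median of -0.05, death targets 0.05, repair targets -0.01 and other p53 targets 0.01, each inside its random range. In the arrest list the kinase gene PLK2 was lower at -1.04, BTG2 was at -0.61 and ZMAT3 at 0.35. Death targets ranged from PIDD1 at -0.71 to TNFRSF10D at 0.62, with FAS at 0.43, BAX at 0.17, BBC3 at -0.09 and TP53I3 at -0.36. DDB2 (-0.87) and RPS27L (-0.66) were the lowest repair targets. Metabolic and redox targets lay below the random range at -0.22, with CPT1C at -1.08, FDXR at -0.95, SAT1 at -0.91 and SESN1 at 0.07. ABHD4, at 10.9 FPKM against 3.94 (1.26), was the other p53 target at least 2-fold higher.

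Metallothioneins and the zinc transporter gene had a median of 2.54 in R282W, with 4 of 5 at least 2-fold higher, and NRF2 targets one of 0.95, with 9 of 19 at least 2-fold higher, among them SLC7A11 (1.70) and GCLM. Heat shock genes had a median of 0.73, with HSPA1B (1.44), HSPA1A (1.27) and HSPA8 (1.09) at least 2-fold higher. For integrated stress response genes the median was 0.55, and 16 of 16 were above 0, with TRIB3 (1.07) highest. Mitochondrially encoded genes (-0.67), histone genes (-0.65), cholesterol synthesis genes (-0.29) and G1/S genes (-0.15, with MCM7 at -1.29) lay below the random range. G2/M genes (0.10, 28 of 34 above 0), interferon-stimulated genes (-0.26), NF-kB targets (-0.19), hypoxia genes (-0.18), Wnt targets (-0.21), ER chaperone genes (-0.08), ribosomal protein genes (-0.05), reference genes (-0.05) and colon epithelial markers (within 0.01 of 0) lay inside it. Outside the lists, SCN1A, a sodium channel gene, was at 3.33 FPKM against 0.18 (1.88), and DBP (-2.12), WNT16 (-2.01), RAB26 (-1.90), the aldolase gene ALDOC (-1.86) and CTDSP1 (-1.79) were among the lowest. The R282W library belongs to another series, so library preparation and mutant cannot be separated. Counts ranged from 50 to 367 for higher and from 150 to 835 for lower genes over the alternative settings.

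**Figure D3:**
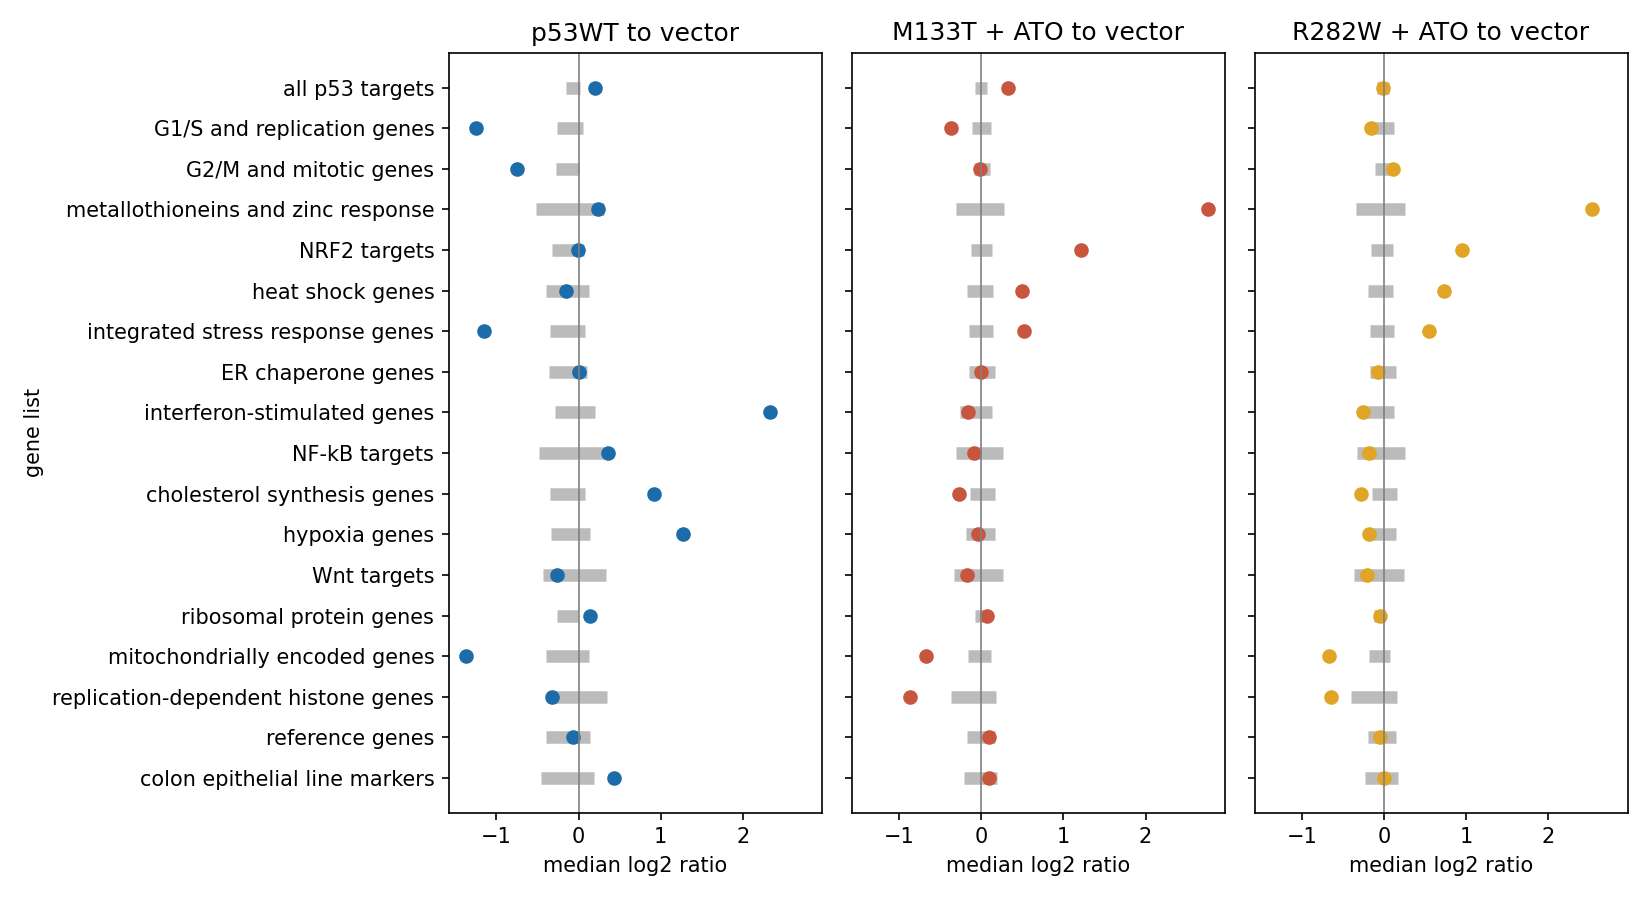
Median log2 ratio to vector of 18 gene lists (points) in p53WT, M133T with ATO and R282W with ATO, with the central 95% of medians of 10000 expression-matched random lists as grey bars. Interferon-stimulated genes stand at 2.33 in p53WT against -0.16 and -0.26 in the other panels, and metallothioneins at 2.76 and 2.54 in the ATO libraries.

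R282W against M133T, both with arsenic, compares the mutants directly. The p53 targets were lower in R282W. CDKN1A was at 40.3 FPKM against 174 (-2.08), BTG2 at 3.76 against 15.8 (-1.82), MDM2 at 97.7 against 262 (-1.41) and PHLDA3 at 7.09 against 20.9 (-1.43). Across all p53 targets the median was -0.31, with 95 of 112 below 0, 7 at least 2-fold lower and none at least 2-fold higher. All 12 arrest and feedback targets were below 0 (median -0.74), including TP53INP1 (-1.30), GDF15 (-0.88) and ZMAT3 (-0.78). Death targets (-0.39), repair targets (-0.39), metabolic and redox targets (-0.26) and other p53 targets (-0.24) also lay below the random range. FAS (-0.82), BBC3 (-0.72), TP53I3 (-0.60), BAX (-0.58), SESN1 (-0.91) and FDXR (-0.77) were lower by less than 2-fold on the log2(FPKM + 1) scale, whereas RPS27L (-1.22) passed that size. In plain FPKM, SESN1, at 3.29 in R282W against 7.04 in M133T, was also more than 2-fold lower.

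Some other lists also differed between the mutants, by medians of a size like those of the smaller p53 lists. NRF2 targets had a median of -0.08, inside the random range, with HMOX1 at -0.27 and ABCC3 at -0.39. Metallothioneins and the zinc transporter gene had a median of -0.21, below the random range, with MT1X at -0.34. Heat shock genes were higher in R282W in 12 of 12 cases (median 0.17), with HSPA1B at 0.47 and DNAJB1 at 0.30. G1/S genes (0.24, 27 of 29 above 0), G2/M genes (0.11, 31 of 34 above 0) and histone genes (0.26) lay above the random range. Below it were ribosomal protein genes (-0.14, 50 of 50 below 0), hypoxia genes (-0.17, with NDRG1 at -0.58) and colon epithelial markers (-0.25, with ELF3 at -0.39). Integrated stress response (-0.04), interferon-stimulated (-0.10), NF-kB (-0.14), cholesterol synthesis (0.02), ER chaperone (-0.03), Wnt (0.03), mitochondrially encoded (-0.09) and reference genes (-0.07) lay inside it. In total 127 genes were at least 2-fold higher and 136 lower, but only 13 and 12 of these were protein-coding. EHMT1, a histone methyltransferase gene, was at 89.4 FPKM in R282W against 31.7 (1.47), SCN1A had a ratio of 2.10, EIF5A2 1.06 and ASAH2 1.62, and ACTA2, which overlaps FAS in the annotation, was lower at -1.65. SLX1B, RN7SL1 and RN7SL2 were also among the extremes, and share reads with copies. Counts ranged from 13 to 291 for higher and from 12 to 339 for lower genes over the alternative settings.

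Against p53WT, both arsenic-treated mutants differed by more genes than against vector. M133T had 605 genes at least 2-fold higher and 790 lower, and R282W had 678 and 929. The p53 targets of M133T had a median of 0.07 against p53WT, inside the random range, but their members went both ways. Death targets lay above it (0.38, 12 of 16 above 0) and metabolic and redox targets below it (-0.25, 12 of 18 below 0). MDM2 (1.55), GDF15 (1.81) and CDKN1A (0.82) were higher and TP53I3 (-0.71) and FDXR (-0.32) lower. For R282W the median of p53 targets was -0.29, with 15 of 112 at least 2-fold lower and 3 higher. CDKN1A (-1.26), TP53I3 (-1.31), FDXR (-1.09) and SESN1 (-0.81) were below p53WT, MDM2 (0.14) and BAX (0.05) were close to it, and GDF15 (0.93) was above it. Among the highest genes in M133T were HMOX1 (5.35), the uridine phosphorylase gene UPP1 (3.62), SLC7A11 (3.26) and CHAC1 (3.24), and in R282W HMOX1 (5.08), UPP1 (3.53), SLC7A11 (3.40) and CHAC1 (3.35).

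Ratios to p53WT share the p53WT library with the first comparison, so groups that stood apart there are on the other side of 0 here by construction wherever a mutant was near vector. In M133T the median of interferon-stimulated genes was -2.61 against p53WT, with IFI27 at -7.60, that of hypoxia genes -1.69 and that of cholesterol synthesis genes -1.23. In R282W the corresponding medians were -2.63, -1.73 and -1.26, with IFI27 at -8.11, ALDOC at -4.48 and the lipoprotein lipase inhibitor gene ANGPTL4 at -4.32. Integrated stress response genes were higher by a median of 1.93 in M133T and 1.84 in R282W, with 13 of 16 at least 2-fold higher in each. G1/S genes had medians of 0.84 and 1.07, and G2/M genes 0.74 and 0.84. Over the alternative settings the counts ranged from 329 to 1088 and 500 to 1292 in M133T, and from 398 to 1160 and 616 to 1511 in R282W.

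Ratios to vector were set side by side across genes to ask how far each PANDA resembled p53WT. Genes are not independent replicates, and the ratios share the vector library. Across 14688 genes Pearson's r between p53WT and M133T was 0.18 (Spearman's rho 0.16), against 0.50 in simulated unchanged libraries. The covariance was 0.049 against 0.053 simulated. A simulated r near 0.50 follows by construction from equal noise in libraries that share a control. An observed r can fall below it when a library has larger differences of its own. A lower r therefore does not show less resemblance than between unchanged libraries. For R282W r was 0.11 (rho 0.05), with a covariance of 0.031, and with protein-coding genes only r was -0.015. M133T and R282W had an r of 0.69 (rho 0.79) and a covariance of 0.15. Among the 112 p53 targets r was 0.28 between p53WT and M133T, -0.11 between p53WT and R282W, and 0.72 between the mutants, where simulation gave 0.47. The covariances of these targets were 0.079, -0.023 and 0.18 in the same order, against 0.032 simulated, so that p53WT and M133T lay below the simulation by r and above it by covariance. Genes at least 2-fold higher in both p53WT and M133T numbered 29, including CDKN1A, BTG2, SERPINB5 and the actin gene ACTA2, which were named after the overlap was seen. Many of the others were non-coding, and the count ranged from 9 with protein-coding genes only to 131 with a pseudocount of 0.1. Independent lists would share 7.56 and simulated unchanged libraries 26.9. For p53WT and R282W the shared higher genes numbered 17, against 6.67 and 26.9, with a range of 2 to 102 over the same settings. Shared lower genes numbered 90 for p53WT and M133T (10.0 for independent lists) and 92 for p53WT and R282W (11.2), against 58.8 simulated. The mutants shared 86 higher genes (2.96 for independent lists, 26.9 simulated) and 178 lower genes (6.07 and 58.8). With 1 vector library the control could not be split, so part of any excess can come from that shared library.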

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

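All tests of explanations given here were chosen after the results were seen. Of 26 lists, 3 had medians against vector outside the random range in opposite directions in 2 groups. These differences were not tested, since each group has 1 library. Integrated stress response genes had a median of -1.15 in p53WT against 0.52 in M133T and 0.55 in R282W, differences of 1.67 and 1.71. Cholesterol synthesis genes had 0.92 in p53WT against -0.27 and -0.29, differences of -1.18 and -1.20. The p53 metabolic and redox targets had 0.52 in p53WT and 0.35 in M133T against -0.22 in R282W, so that R282W stood -0.73 and -0.56 from them.

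The first 2 of these lists belong to a wider pattern in the p53WT library, in which interferon-stimulated, hypoxia and cholesterol synthesis genes were higher and replication and stress response genes lower than in vector. Removing a fitted trend on GC content and transcript length left the medians at 2.35 (interferon-stimulated), 1.24 (hypoxia), 0.92 (cholesterol synthesis), -1.22 (G1/S) and -1.16 (stress response), and the trend took up 0.43% of the variance between genes, which argues against such a bias as the whole cause. For blood, fibroblast, endothelial and liver markers, the highest of the 4 list medians in p53WT was 0.14 FPKM, so no list was high as a whole. Single markers stood above that, with HBB at 19.15 FPKM (12.64 in vector), COL1A1 at 6.12 (7.72) and SERPINA1 at 5.57 (1.81). LYZ was at 4.24 (0.38) and CD74 at 1.11 (0.13). A list median cannot show a small share of such cells or a single blood cell type, so these were not excluded. Activation of p53 targets did not come with higher interferon-stimulated genes in M133T (median -0.16). That library also had arsenic and a mutant p53, so this cannot decide the question, and wild-type p53 stays open. The culture or preparation of the single p53WT library may equally set these groups apart and cannot be told apart from wild-type p53.

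The p53 targets were lower in R282W than in M133T. Rows set beside the wrong genes are argued against by an r of 0.991 between the mutants over the 312 rows out of order, once joined by symbol. A weaker arsenic exposure of the R282W cells could not be decided, since heat shock genes were higher there (median 0.17) while metallothioneins were lower (-0.21), and the rule of this test was made more cautious after its first outcome was seen. Preparation in an earlier series cannot be told apart from the mutant, and 8 of 17 lists other than p53 targets also lay outside the random range between these libraries. A difference between the mutants in their response to arsenic, which the design names, stays open and untested.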

How the results depend on the processing

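The alternatives with 5 FPKM, a pseudocount of 0.1, protein-coding genes only and a trimmed mean over 4 libraries were chosen after seeing the data. Each of 22 main results was recomputed under each alternative, except that the trimmed mean over the 3 libraries of the series leaves out R282W and covers 11 of them, which gave 165 values, of which 1 reversed and 40 moved. Under median-of-ratios scaling, equal sums, both trimmed means and no filter all counts stayed within 1.5 times and all correlations within 0.05, bounds set when the alternatives were run. The p53 target medians kept their place inside or outside the random range in every setting, with ranges of 0.19 to 0.30 (p53WT), 0.24 to 0.36 (M133T) and -0.03 to 0.05 (R282W) against vector, and -0.35 to -0.27 for R282W against M133T. With at least 5 FPKM, fewer genes were counted by construction: 319 higher and 341 lower (p53WT against vector), 108 and 149 (M133T), 92 and 183 (R282W), 44 and 50 (R282W against M133T) and 502 lower in M133T than in p53WT. With protein-coding genes only, also fewer by construction, the counts were 253 and 271 (p53WT), 71 and 124 (M133T), 50 and 150 (R282W), 329 and 500 (M133T against p53WT), 398 and 616 (R282W against p53WT) and 13 and 12 (R282W against M133T). There the correlation with p53WT was 0.091 for M133T with 9 shared higher genes, and -0.015 for R282W, the reversed value, with 2 shared. With a pseudocount of 0.1 the counts were 808 and 1014, 427 and 721, 367 and 835, 1088 and 1292, 1160 and 1511, and 291 and 339 in the same order. The correlations were 0.27 with 131 shared genes (M133T) and 0.21 with 102 (R282W), and the cause was not tested. Of 656 list medians under alternatives 9 moved by 0.25 or more and 0 reversed, and of 4762 gene ratios 73 changed their side of 2-fold and 0 reversed. No paired analysis was possible because each group has 1 library, and no library could be left out. Settings on read counts that the design held (at least 100 reads, a prior count of 0.5, and thinning to equal depth) were not run because the files hold no counts. The unknown depth limits genes with low values most.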

Other observations

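A list of clock output genes was chosen after DBP, which it includes, was seen among the lowest genes, and it was set against no random lists. Its median log2 ratio to vector was -1.30 in M133T, with 5 of 9 measured genes at least 2-fold lower, and -1.12 in R282W, with 6, against 0.26 in p53WT, with 0. DBP, a transcription factor driven by the circadian clock, had ratios of -1.97 and -2.12, and the period genes PER1 (-1.38 and -1.63) and PER2 (-1.49 and -1.56) and the factor TEF (-1.30 and -1.39) were also lower. NR1D2, a clock repressor, was near its vector level at 0.13 and 0.01.

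Globin genes, a list chosen after HBB was seen, had medians of -1.82 in M133T and -1.40 in R282W, with 4 of 5 measured genes at least 2-fold lower in each, and 0.18 in p53WT. HBB, which encodes adult beta globin, was at 19.2 FPKM in p53WT, 12.6 in vector, listed at 0 in M133T and at 0.07 in R282W. HBG2 stood at 10.5 FPKM in p53WT, 5.82 in vector and 1.78 and 1.91 in the mutants. The embryonic gene HBE1 was the highest globin in all libraries, at 110 FPKM in p53WT, 97.0 in vector, 104 in M133T and 81.7 in R282W. HBA1 and HBA2 are near-identical and uncertain.

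The tests of the next pattern were all chosen after its result was seen. NRF2 targets and metallothioneins were higher in both arsenic-treated libraries. Activation of p53 targets as the cause could not be excluded, although NRF2 targets had a median of 0.95 in R282W, where p53 targets as a list were near vector, since this is 1 library and GDF15 was higher there. Arsenic itself may raise them, and p53WT without arsenic, with a median of -0.00051, does not speak against it. It cannot be told apart from the mutants, because no arsenic-treated vector library was analysed here.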
